A study of Homo sapiens with 2 samples.

How the data were processed

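Nascent RNA was measured by precision run-on sequencing (PRO-seq) in K562, an established human chronic myelogenous leukaemia line with erythroid features. In this assay polymerases engaged on DNA extend their transcripts with biotinylated nucleotides in permeabilised cells, and the labelled RNA is pulled down and sequenced. The run-on lasted 5 min at 30 °C and the libraries were made with a directional RNA kit, per the labels' protocols. There were 2 libraries, 1 from untreated cells and 1 from cells kept in 0.1% DMSO for 1 h, and each treatment therefore had 1 library.

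The deposited table held the read count of each library over 36814 windows of 6000 bases, each reaching 3000 bases to either side of the annotated start of a gene on the human genome hg38. Reads were aligned with Bowtie2 2.3.5 and counted with featureCounts 2.0.1, per the submitters' processing notes. The authors' TPM values in the same table equalled the CPM (counts scaled to the library's total) in all 36814 windows (tolerance 1e-06), since all windows have 1 length, and were not used further. CPM were therefore computed from the deposited counts. The column with the authors' mean TPM was not used.

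How the counts were assigned was read from the counts themselves. All 1154 windows whose every base is also covered by another window held 0 reads, and these included 321 windows covered only by windows of the opposite strand. Reads in shared bases were thus absent from the counts whatever the strand, although the kit keeps strand information, and a read cannot be assigned to a gene or to its antisense partner. In all, 14279 windows (38.8%) shared a base with another, and 8739 had under 1 kb of their own, with a median of 0 reads. Genes such as GAPDH are at 0 for this reason. Of the windows, 23342 (63.4%) matched a symbol of the RefSeq table of GRCh38.p14, and 2656 of these (11.4%) did not hold that gene's RefSeq start. Exons and introns were not used here, and values are given per window.

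The totals were 2136291 reads for the untreated and 4154920 for the DMSO library. Because 4 windows over 45S ribosomal RNA repeats took unequal shares of the 2 libraries, counts were scaled with the TMM factors of edgeR 4.0.16 (R 4.3.3), with effective sizes that put equal levels at 3.81 DMSO reads per untreated read. The log2 DMSO/untreated ratio used a prior count of 0.5 reads. The expression floor was a mean of 5 CPM and 100 reads over both libraries, which 6591 windows passed. Under TMM the median window past the floor stood at a log2 ratio of 0.31, and under library totals at 1.27, so single ratios are given relative to this median. The spread between the libraries was the square root of edgeR's common dispersion. Intervals at 95% are exact Poisson intervals for counts and exact Clopper-Pearson intervals for ratios and shares; reads carry no molecular identifiers, so all of them cover counting error only. Against a count of 0, a ratio is given as a bound computed from 3 reads. The exact Poisson interval of a count of 0 reaches 3.69 reads, so this bound lies above the lower limit of the exact interval.

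With 1 library per treatment there was no replicate check and no p-value. Before the data were examined, 28 gene lists, the floor, the 2-fold threshold and a rule for named genes were fixed. The rule took the 10 windows of highest mean CPM and of highest CPM per kb of unshared length (200 bases or more), the 12 highest and 12 lowest ratios past the floor, the 3 windows with most reads in either library against 0 in the other, and from each list the 4 members of highest mean CPM and the most extreme ratios. Ribosomal RNA and mitochondrial windows were kept out of the rankings, and genes of the Y chromosome were not named. Some windows that the rule selects are not reported here. A list's median ratio, taken relative to all windows past the floor, was placed among 10000 random lists of equal size matched on mean CPM in 20 bins. A list stood apart under percentile 2.5 or above 97.5; lists with fewer than 5 members past the floor were not scored.

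The procedure was tested on simulated data with the means and library sizes of the 6591 windows past the floor and 200 changed windows. With counting error alone, 100% of the 4-fold changes in either direction lay past 2-fold, and 0.125% of the unchanged windows did. With the spread between the libraries added, 86% of the 4-fold rises and 94% of the 4-fold falls did, and 20.6% of unchanged windows. Of 200 random lists of 15 windows, 4.5% stood apart in that simulation, and 64% of 100 lists shifted 1.5-fold. Alternatives covered the scaling (library totals, DESeq2 1.42.0 size factors, upper quartile), the floor, the prior count, thinning of the DMSO library, short windows, gene families, the fold threshold, the list statistic and its matching. Added after seeing the data were windows without overlap, subtraction of the trend with read count, centring on the median, thinning to equal reads outside ribosomal and mitochondrial windows, and leaving out neural windows. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.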

Results

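The series profiled nascent transcription in unperturbed K562 cells with 2 PRO-seq libraries, 1 untreated (2136291 reads) and 1 from cells in 0.1% DMSO, a common drug solvent (4154920 reads). Outside ribosomal RNA and mitochondrial windows the untreated library held 525322 reads (24.6%) and the DMSO library 2249790 (54.1%). Reads fell in 18424 windows of the untreated and 28585 of the DMSO library, and 17724 windows held reads in both. The median window past the floor held 45 untreated and 205 DMSO reads. Reads of mature RNA were not separated from nascent RNA here, so levels may include both. No value has a replicate check.

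The most densely read gene starts included short noncoding RNA genes, a microRNA host and genes of the long arm of chromosome 22. The window of GSTA4 (chromosome 6, 52992305 to 52998304), which also holds RN7SK, the RNA that keeps the elongation factor P-TEFb inactive, had 2148 untreated and 10129 DMSO reads. The window of NEMF, which holds the signal recognition particle RNA gene RN7SL3, had 3114 and 9561 reads. MIR17HG, host of the miR-17 cluster, had 464 and 4730 reads, and NEAT1, the RNA scaffold of paraspeckles, 783 and 3343. GP1BB, a platelet glycoprotein gene at chromosome 22, 19719945 to 19725944, had 591 and 5345 reads, and its window also overlaps SEPTIN5. Per kb of unshared bases, the window AP000769.2 over MALAT1 ranked high with 752 CPM per kb, as did TSPOAP1, whose window holds MIR142, with 280, and YDJC on chromosome 22 with 204. MTRNR2L8 had the highest mean, 7262 CPM, but it is nearly identical to mitochondrial ribosomal RNA, as are MTRNR2L12 and MTRNR2L1, and their levels are uncertain.

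Genes of the cell line's own lineage were transcribed and most genes of other lineages were near 0. Of 36 erythroid windows, 27 reached 1 CPM in both libraries, as did 247 of 476 zinc finger and 56 of 87 ribosomal protein windows. Few reads suffice for this level, since 3 reads make 1.40 CPM in the untreated library. TFRC, the transferrin receptor, had 202 CPM untreated and 284 CPM with DMSO, KLF1, an erythroid transcription factor, 110 and 194 CPM, the fetal globin gene HBG1 114 and 125 CPM, and TAL1 54.8 and 91.5 CPM. CPM are scaled to library totals, of which ribosomal RNA windows took 71.5% untreated and 42.2% with DMSO. The 2 CPM values of a gene therefore do not compare the libraries. As log2 ratios relative to the median window, TFRC stood at -0.79, KLF1 at -0.45, HBG1 at -1.15 and TAL1 at -0.54. Of 19 megakaryocytic windows 6 reached 1 CPM in both libraries, led by GP1BB, TUBB1 with 27.6 and 44.5 CPM, and ITGA2B with 13.1 and 20.2 CPM. Of the granulocytic and monocytic windows 4 of 20 did, led by CD68 with 94.1 and 289 CPM in a window that also overlaps EIF4A1, as did 5 of 21 lymphoid windows and 2 of 16 epithelial, fibroblast and hepatocyte windows. None of the 14 windows in 9p21, a segment that K562 has lost in part, did. The 14 windows held 2 untreated and 56 DMSO reads in all, of which KLHL9 had 0 and 38. Windows with under 1 kb of unshared bases can hold few reads. They numbered 3 in 9p21, 6 among erythroid, 4 among megakaryocytic and 1 among granulocytic and monocytic windows. There were 2 among lymphoid and 2 among epithelial, fibroblast and hepatocyte windows. In the BCR-ABL and JAK-STAT list 18 of 22 windows reached 1 CPM, with BCR at 62.7 and 503 CPM, PIM1 at 312 and 324 CPM and CRKL at 108 and 236 CPM. As log2 ratios relative to the median window, BCR stood at 1.73, PIM1 at -1.22 and CRKL at -0.15.

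The comparison of DMSO with untreated cells asks how far a solvent control resembles unperturbed cells, and here it is a comparison of 2 libraries rather than of conditions. The libraries agreed in rank with Spearman's rho of 0.730 and Pearson's r of 0.768 across the 6591 windows past the floor, where windows are not independent replicates. Counting error alone would have left a rho of 0.963. Over all 29285 windows with a read, rho was 0.828 and r 0.928. The coefficient of variation beyond counting error was 35.3% on the TMM scale and 64.8% with library totals. Relative to the median window, 464 windows were at least 2-fold higher with DMSO and 525 at least 2-fold lower, against means of 12.1 and 0.71 from counting error alone over 100 simulations. Together they made up 15% of the windows. In simulated data with that spread in each library 20.6% of unchanged windows lay past 2-fold, but the spread was estimated from the same 2 libraries, so an excess over it could not be tested. Intervals, which cover counting error only, lay wholly past 2-fold for 93 of the higher and 183 of the lower windows. In the simulation with that spread, such intervals held the true ratio in only 44.6% of unchanged windows. On the TMM scale itself the counts were 991 higher and 222 lower, so that 81.7% of them were higher, against 46.9% relative to the median and 99.3% with library totals. The ratio also moved with read count, from a median of -0.24 in the windows of 100 to 127 reads to 0.13 in those with 615 or more. These are reads of both libraries together, most of them DMSO reads. A high DMSO count thus raises both the read count and the ratio, and part of the trend may follow from this.

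**Figure D1:**
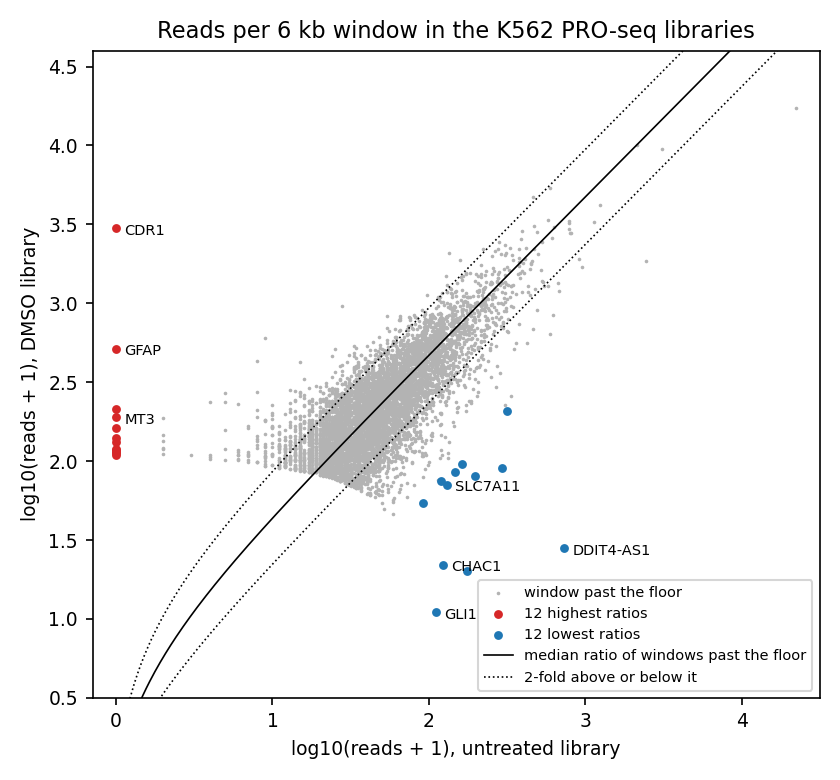
Each point is a window past the floor, outside ribosomal RNA and mitochondrial windows, placed by log10(reads + 1) in the untreated (x axis) and the DMSO library (y axis); the solid line is the median ratio and the dotted lines lie 2-fold to either side. The 12 highest ratios, in red, all had 0 untreated reads, with CDR1 at 2985 DMSO reads, and the 12 lowest, in blue, include DDIT4-AS1 and CHAC1.

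All 12 windows of highest ratio had 0 untreated reads, and several of them belong to genes known from nervous tissue. The window of CDR1 (X chromosome, 140781367 to 140787366), which also overlaps LINC00632, had 2985 DMSO reads. With 3 reads in place of the untreated 0, CDR1 was 211-fold higher relative to the median. GFAP, an intermediate filament gene of astrocytes (chromosome 17, 44913938 to 44919937), had 514 reads, 36.3-fold higher by the same bound. MT3, a brain metallothionein, had 188 reads, the neurotrophin receptor gene NTRK2 119, and BEX3 108. AL117190.2 in the imprinted MEG3 locus had 214 reads, and 3 windows of the imprinted SNHG14 locus on chromosome 15, among them the window named SNHG14 with 132, had 116 to 161. AC008738.7 next to SLC7A10 had 139 reads, and AL354953.1 next to NMNAT2 111. Of 46 further neural genes, listed after these windows were seen, 8 (17.4%) had intervals wholly above 2-fold on the TMM scale, against 1 of 41 granulocytic, monocytic and lymphoid windows and 1.05% of all windows. Lists of liver, of muscle and heart, and of other organs gave 3 of 43 (6.98%, interval 1.46 to 19.1). That interval holds the neural share. In the opposite direction the windows with most untreated reads against 0 DMSO reads were AC016394.1 with 8, DSC2 with 6 and AC012181.2 with 5.

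Several of the lowest ratios lay at genes known from the amino acid and integrated stress response. DDIT4-AS1, whose window (chromosome 10, 72272981 to 72278980) overlaps the stress-induced gene DDIT4, had 732 untreated and 27 DMSO reads, a log2 ratio of -6.96 relative to the median (interval -7.61 to -6.45). CHAC1, which degrades glutathione and is a target of the transcription factor ATF4, had 122 and 21 reads (-4.73, interval -5.52 to -4.10). SLC7A11, the cystine transporter gene, had 129 and 70 reads (-3.11, interval -3.56 to -2.69), and the stanniocalcin gene STC2 118 and 74 (-2.90). GLI1 had 110 and 10 reads (-5.59) in a window that also overlaps INHBE, and MIOX 175 and 19 (-5.38) in one that overlaps ADM2. AL157871.2, inside WARS1, stood at -3.93 and AC126696.2, by SLC7A5, at -2.85. AC087190.2 stood at -3.53 and FAM83A-AS1 at -3.02, AC006504.1 had 91 untreated and 53 DMSO reads, and LINC02252 had 162 and 95.

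Of the 28 lists 18 could be scored, and 4 stood apart where 0.9 would among random lists. Random lists hold unrelated windows, so 0.9 is not the number to expect for genes that are regulated together. The unfolded protein and integrated stress response list had a median of -0.40 relative to the median window (percentile 1.44), with 9 of its 14 members below the median window and 5 at least 2-fold lower. Those 5 were CHAC1, SLC7A11, ASNS (-2.45), PSAT1 (-1.90) and SESN2 (-1.23); ASNS and PSAT1 were chosen after their values were seen, and the window of ASNS does not hold its RefSeq start. ATF4 itself stood at 0.39 and the protein-folding genes CALR and PDIA4 at 0.56 and 1.00. The list no longer stood apart with a floor of 20 CPM and 400 reads, where its median was 0.16 over 6 members, nor when the DMSO library was thinned to equal reads outside ribosomal and mitochondrial windows, where it was -0.20 at percentile 54.8. Those settings were tried besides the main one, the latter after the data were seen. The floor of 400 reads counts both libraries together, most of them DMSO reads. It therefore tends to drop members with low DMSO reads, such as CHAC1 and SLC7A11, although SESN2 stayed. The sign at that floor is thus not independent of the ratio.

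Erythroid genes had a median of -0.35 (percentile 1.86), with 11 of 16 members below the median window; HBG1 stood at -1.15 and TFRC at -0.79, and XK at 0.50. The list did not stand apart at a floor of 1 CPM and 20 reads (-0.18, percentile 9.54), with any read (percentile 5.82), by its mean (percentile 3.24), or after thinning to equal reads outside ribosomal and mitochondrial windows (percentile 3.35). Replication-dependent histone genes had a median of -0.38 (percentile 0.58), with 17 of 18 members below; HIST1H1C, a linker histone gene, stood at -1.17 and HIST1H4C at 0.27. They stood apart under all alternatives that kept the list, though HIST1H4J, HIST1H4K and other near-identical copies have uncertain levels. Glycolysis and hypoxia genes had a median of 0.55 (percentile 98.68), with 6 of 8 members above; TPI1 stood at 0.78, PFKL at 0.92 and KDM3A, in a window without its RefSeq start, at 2.38, and SLC2A3 at -1.09. With any read in either library the median was -0.29, and the list did not stand apart at the other floors (percentiles 83.2 and 95.65), by its mean (96.2), with random lists matched on length too (95.4), in windows without overlap (94.8) or after the thinning just named (96.9). The 4 lists stood apart as well when the neural windows above were left out.

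**Figure D2:**
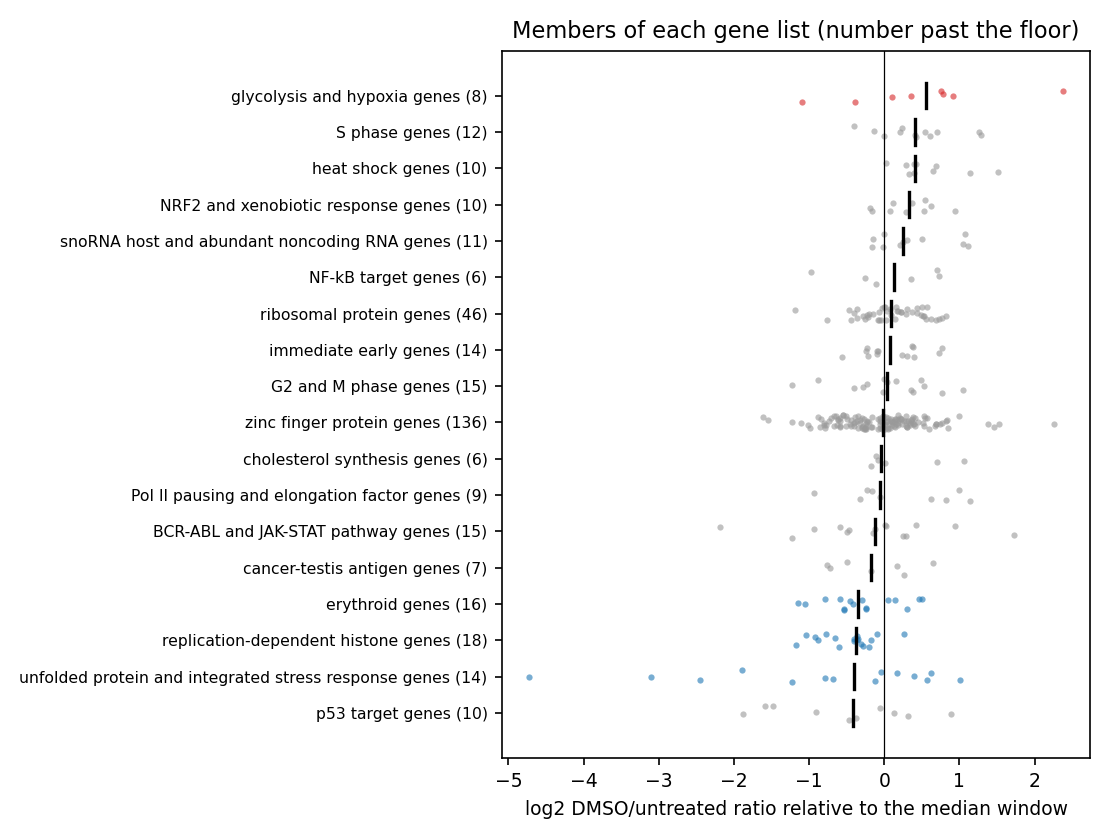
Each point is a list member past the floor, placed by its log2 DMSO/untreated ratio relative to the median window (x axis), with 1 line per list and the number of members in parentheses; black bars are list medians. Lists in blue (unfolded protein and integrated stress response, replication-dependent histone, erythroid) and red (glycolysis and hypoxia) stood apart from random lists, and lists in grey did not in the main setting.

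The other 14 lists did not stand apart in the main setting. All 10 heat shock genes lay above the median window, with a list median of 0.41 (percentile 95.84), among them HSPH1 at 1.51 and STIP1 at 0.69. S phase genes had a median of 0.41 (percentile 96.83), with CCNE1 at 1.28 and E2F1 at 1.26, and NRF2 and xenobiotic response genes 0.33 (percentile 92.61). The p53 target genes had -0.42 (percentile 4.51), with 7 of 10 members below the median window and 3 at least 2-fold lower; TIGAR was lowest at -1.87 in a window that overlaps CCND2 and does not hold the RefSeq start, and ZMAT3 highest at 0.89. Immediate early genes, often induced within the hour by handling, had a percentile of 56.54, with JUND at 0.77 and EGR1 at -0.57. Percentiles were 15.61 for BCR-ABL and JAK-STAT genes, 38.78 for cholesterol synthesis, 67.80 for NF-kB targets, 63.31 for G2 and M phase, 41.23 for Pol II pausing and elongation factors, 84.91 for snoRNA hosts and abundant noncoding RNAs, 64.6 for ribosomal proteins, 45.3 for cancer-testis antigens and 46.14 for zinc finger proteins. In the BCR-ABL list BCR stood at 1.73 and STAT5B at -2.18, the latter in a window that does not hold the RefSeq start. Some of these lists stood apart under other settings. Heat shock genes did by their mean (percentile 98.94), with the trend subtracted (98.06) and without ribosomal, mitochondrial, small RNA and histone windows (97.59). S phase genes did under the last of these (97.91) and after thinning to equal reads outside ribosomal and mitochondrial windows (99.43), as did Pol II pausing factors after that thinning (98.35). The p53 targets did by their mean (1.91) and with matching on length too (1.90), BCR-ABL genes with that matching (2.325), and cancer-testis antigens with any read (0.11).

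Longer genes had higher DMSO/untreated ratios. In the 4101 windows past the floor that share no base and hold the RefSeq start, all of which have a length, the longest 20% of genes stood 0.33 above the shortest 20% (bootstrap interval over genes 0.26 to 0.42). Over all windows past the floor the check was void, since 77.8% had a length.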

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

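Reads outside the comparisons of gene starts were counted in ribosomal and mitochondrial windows. They are given because they lie outside the main measurement. The 4 windows over 45S ribosomal RNA repeats on chromosome 21 held 71.5% of the untreated and 42.2% of the DMSO reads. Windows of the mitochondrial chromosome held 3.94% and 3.70%. Their reads were kept in the library totals and out of the named rankings. Comparisons of groups or outlying replicates could not be made with 1 library each.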

How the results depend on the processing

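No paired analysis was possible because each treatment has 1 library, and leaving out a replicate was not possible either. Neither the prior count, the centring nor the subtraction of the trend enters the spread or the rank agreement, and scaling does not enter the latter, so these have no such value. The cause of the differences below was not tested, except that floors and thinning change how many windows are counted. Windows without overlap, thinning to equal reads outside ribosomal and mitochondrial windows, trend subtraction, centring and leaving out neural windows were chosen after the data were seen.

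The spread between the libraries was 0.648 with library totals, 0.389 at 1 CPM and 20 reads, 0.411 with any read, 0.340 after thinning to equal totals, 0.328 after thinning to equal reads outside ribosomal and mitochondrial windows, and 0.347 without neural windows, against 0.353. The rank agreement was 0.855 at 1 CPM and 20 reads, 0.575 at 20 CPM and 400 reads, 0.828 with any read, 0.648 and 0.547 after the 2 thinnings and 0.777 without overlap. Windows at least 2-fold higher (991) and lower (222) numbered 4352 and 31 with library totals, 2059 and 1003 at 1 CPM, 265 and 37 at 20 CPM, 13111 and 3742 with any read, 490 and 462 with the trend subtracted, 464 and 525 centred on the median, and 2196 and 675 at 1.5-fold; thinning gave 620 and 250 higher, and windows without overlap 67 lower. At 1 CPM and at 20 CPM 2 lists stood apart; elsewhere 3 to 5 did. The longest minus shortest genes gave 0.48 with any read, where lengths are known for too few windows. Of the erythroid windows 17 reached 5 CPM in both libraries. The stress response list reversed to 0.16 at 20 CPM and the glycolysis list to -0.29 with any read. The floor behind the first reversal tends to drop members with low DMSO reads. Scaling and centring shift nearly all windows alike and so leave list percentiles in place; under the other settings the 4 lists that stood apart still did 38 times, and 11 times kept their sign without standing apart. With library totals, which add 0.97 to log2 ratios before the prior count, the 12 lowest windows left their intervals. The 12 highest have no upper bound to pass. At their 0 untreated reads the prior count makes the change smaller, as for CDR1 from 11.88 to 12.14. DESeq2 size factors change ratios by -0.02 only, before the prior count. Depth limits the untreated library most: 1007 windows held 100 reads in it, against 5824 with DMSO.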

Other observations

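The tests on neural RNA, on a mixture of tissues, on depth and on 9p21 reads were chosen only after the result was seen, and windows without overlap, the subtraction of the trend and thinning to equal reads outside ribosomal and mitochondrial windows only after the data were. The first 2 tests stand in place of earlier ones limited to list members with 20 or more reads, which were void because that limit keeps, of genes silent in K562, those with DMSO reads. The neural, other tissue and second ATF4 target lists were drawn up after the named windows had been seen but without the values of their own genes, except that windows next to SLC7A5 and WARS1 were known, and the chromosome 22 segment was noticed in these data.

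Reads at CDR1, GFAP, MT3 and 9 other windows appeared in the DMSO library and were absent from the untreated one. Lower depth of the untreated library is argued against, since 13 of all 6591 windows past the floor had 0 untreated reads, where sampling at the scaled depths gives an expected number of 1.19e-08, with an upper interval bound of 3.69 windows. Of a further list of 46 neural genes, none among those 12 and 3 with 20 or more untreated reads, 8 (17.4%, interval 7.82 to 31.4) lay wholly above 2-fold on the TMM scale, against 1 of 41 granulocytic, monocytic and lymphoid windows (2.44%, interval 0.06 to 12.9) and 1.05% of all windows; SYT1 had 0 and 80 reads, BEX1 0 and 74 and SOX2 0 and 61, but MBP had 1 and 8. Lists of liver, of muscle and heart, and of other organs gave 3 of 43 (6.98%, interval 1.46 to 19.1), among them TF with 0 and 58 and CYP3A4 with 0 and 38; the neural share lies within that interval, so RNA of neural cells and RNA from a mixture of tissues both stay open, and whether the reads came from other samples by index hopping or carry-over was not tested. On the TMM scale reads in 9p21 were 7.35-fold higher with DMSO (interval 1.94 to 62.2), but 2.36-fold (interval 0.57 to 21) without KLHL9, which leaves open whether cells with that segment intact contributed.

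The stress response list had a median DMSO/untreated ratio below that of the median window, with 9 of 14 members below and 5 above, and the opposite sign (0.16) at a floor of 20 CPM. That floor also asks for 400 reads over both libraries, most of them DMSO reads. It tends to drop members with low DMSO reads, so the sign there is not independent of the ratio. Overlapping windows or windows away from the gene start are argued against, since the list's percentile was 0.03 in windows without overlap that hold the RefSeq start. After subtraction of the trend with read count the percentile was 1.39. The random lists were already matched on mean CPM, so the subtraction could hardly move the percentile and does not decide on that trend. Thinning to equal totals kept the list apart (2.15), but thinning to equal reads outside ribosomal and mitochondrial windows did not (54.8, median -0.20). Higher transcription of ATF4 targets in the untreated culture is a hypothesis that a second list of 28 such genes does not decide: 8 of its 9 members past the floor lay below the median window, with a median of -0.46 and a percentile of 3.36. Of these 9 only EPRS (-1.53) and SARS (-1.45), named for their values, were at least 2-fold lower, and NARS (0.25) lay above. With 1 library per treatment, DMSO cannot be told apart from culture, day or library.

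Read density was high on chromosome 22 up to the end of BCR, which is fused to ABL1 in K562. The 59 windows past the floor there had a median of 19.6 untreated and 94.5 DMSO reads per kb, 3.18 and 3.26 times the rest of the chromosome and above all 5053 runs of as many neighbouring windows on other chromosomes (percentile 100 in both). Overlapping windows are argued against, as the percentile was also 100 in 21 windows without overlap. Gene density stays open, since the runs were not matched on it. The segment was noticed in these data, so its percentile describes it and is no test. Extra copies of the fused segment are a candidate explanation; on its ABL1 side, 6 windows within 500 kb after the end of ABL1 reached percentiles of 98.7 untreated and 97.2 with DMSO, which does not settle it for that side. Copy number was not measured here.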
